A study of Rattus norvegicus with 6 samples.

How the data were processed

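Total RNA from myocardial tissue or cultured cells was extracted with a Qiagen column kit and labelled with Cy3 by Agilent's Quick Amp kit, per the labels. All 6 arrays were of 1 rat design and lay on 1 slide in 1 scan, so slide and scan date could not be tested as batches; the myocardial and cell arrays lay in different rows of the slide. The authors deposited the scanner output of each array, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes, which holds intensity values (processed signal, median signal and background) for 58717 spots. They also deposited a table of log2 values, whose making is not given in the sources used here. Set against the scanner signals, its columns followed log2 processed signal in the same direction (r of 0.9998 or more on each array) with equal medians over the 4 myocardial arrays (8.85) and over the 2 cell arrays (9.67). It was used as an alternative.

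Each array's log2 processed signal was taken relative to its own 75th percentile, which was a signal of 772 in sham, 1120 in PBS, 1276 and 1058 in treated replicates 1 and 3, 2360 in unlabelled and 2615 in labelled cells. Control spots and outlier-flagged spots were left out, and the spots of a probe were averaged. The scanner files used here hold no gene names, so names came from matching each probe's unversioned accession to a table of RefSeq genes (assembly GRCr8, used for names only, since the file headers name an older build). Of 30367 probes, 18355 received a symbol and 12012 did not. The brightest probe stood for a gene and an unnamed probe for itself, giving 26773 features, 15424 of them named genes. Symbols may hide paralogs that share a probe. The files used here hold no mean signal column, so the normexp alternative (offset 50) used the median signal in its place.

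Comparisons were PBS against sham, treated against PBS, treated against sham, and labelled against unlabelled cells. Features well above background on every array compared were counted when 2-fold apart, in both treated arrays where that pair entered. A gene measured on only one side received a bound: the bright mean against the higher of the dim array's lowest signal among probes well above background and the probe's own signal. That lowest signal is not a detection limit, since other probes with higher signals were not well above background. Bounds given as at least a fold therefore hold only against the signal used. Comparisons with the treated pair were also tested with limma 3.58.1 (R 4.3.3; lmFit and eBayes, Benjamini-Hochberg adjustment) in 1 fit of the 4 myocardial arrays, over 19235 features well above background on at least 1 of them. The replicates are not stated to be separate animals, so p-values measure only the spread between these 2 samples, which may be technical.

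Gene lists, 30 of programs and 18 of cell type markers, were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives. They held 751 members, of which 679 were on the array. Lists were tested with camera (preset correlation 0.01) where limma was used. Its p-values set a list's genes against the other genes on these arrays, so they do not measure the spread between animals. In every comparison the list's median was set against 10000 random lists matched on mean expression in 20 bins, as a description of these arrays. Lists with fewer than 5 measured genes received no percentile, and no marker of the list for sex was on the array. Named genes are the 10 highest and 10 lowest of each comparison among those well above background on every array compared (by the smaller difference where the treated pair entered), up to 5 each way measured on only one side, and up to 4 members of a list. A gene that this rule names is not reported here.

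The fit was tested on simulated data with the spread of these arrays, for treated against PBS over 19235 features. At an adjusted p under 0.05 it recovered 0% of genes changed by a log2 of 1 or 2, 76.0% of those changed by 4 and 96.0% of those changed by 6, with 7 unchanged features passing. The 2-fold rule recovered 26.0% of genes changed by 1 and 82.0% of those changed by 2, with 198 unchanged features passing out of 17027 features well above background on the arrays compared. Of 100 simulated lists of 20 genes moved by 0.5, camera at an unadjusted p under 0.05 called 100% with the preset correlation and 0% with an estimated one. Of unmoved lists it called 2% and 0%. Genes were simulated independently of each other, so false calls from co-expressed lists could not appear. Figures were drawn with matplotlib 3.10.9. Alternatives covered background correction, normalization, the filter on dim probes, the choice of probe, the variance model, thresholds, the correlation in camera and single treated replicates.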

Results

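Gene expression was measured on 6 one-colour arrays from Sprague Dawley rats aged 13 weeks. The series set out to follow adipose-derived stem cells (ADSCs, mesenchymal cells grown from fat) that carry hexadecyl-4-124I-iodobenzoate, a lipophilic tracer with a positron-emitting iodine, in a rat model of myocardial infarction and in culture. Of the 4 myocardial arrays, 1 came from sham-operated myocardium, 1 from infarcted myocardium injected with buffer (PBS), and 2 from infarcted myocardium that received labelled ADSCs, called treated here and numbered replicates 1 and 3 in the labels. Tissue was taken at 21 days, which the labels count from a sham operation for all 4 myocardial arrays, infarcted tissue included, so the time since infarction or injection is unclear. The other 2 arrays held labelled and unlabelled ADSCs at 14 days of culture, 1 each. The share of probes well above background ran from 64.4% in sham to 69.4% in unlabelled cells, and no spot was saturated. The number of arrays limits the precision: sham, PBS, and both cell conditions have no replicate, so errors are given only where the treated pair supplies them, and the labels do not say whether that pair came from separate animals.

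The first comparison asked how infarcted, PBS-injected myocardium differed from sham myocardium. A few atrial genes stood far higher on the PBS array, the atrial and matrix lists stood moderately higher, and the mitotic and erythroid lists lower. Myl7, the atrial regulatory myosin light chain, was 268-fold higher (log2 difference 8.07), and Mybphl, a myosin-binding protein of atrial muscle, was 114-fold higher. Sln, the atrial calcium pump regulator sarcolipin, was measured only on the PBS array, at least 2730-fold above the sham bound. Msln, a mesothelial surface protein, was at least 203-fold higher by the same bound. Other genes at the top were Reg3b (22.5-fold), Ccl21 (21.4-fold), Cdhr1 (21.4-fold), Sbk2 (19.1-fold), the iron hormone Hamp (17.8-fold), the complement gene C4a (16.2-fold), Btla (13.3-fold) and the Wnt antagonist Sfrp2 (13.0-fold). Bounds for Wfdc21, Rab15 and Atp1b4 were at least 125-fold, 100-fold and 74.2-fold higher. Among the lowest genes measured on both arrays were Cd1d1 (log2 difference -3.14), C2h3orf33 (-2.85), Cfap52 (-2.63), Slco1a4 (-2.34), Pla2g2c (-2.26), Slc31a1 (-1.89), Rhox5 (-1.87), Pdzk1 (-1.83) and Polr3c (-1.78), and by bounds Lrr1 was at least 45.1-fold, Ly6cl1 16.9-fold and Kcnk10 13.1-fold lower. Reg3b, C4a and Ccl21 have close relatives in the rat genome, so their probes may report more than 1 gene. Btla was read from the brighter of its 2 probes, and the other was not looked at singly.

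Among lists of genes fixed beforehand, those of scar and contractile stroma stood high on the PBS array. Of 20 measured fibrillar matrix genes, 18 were higher than in sham, with a median log2 difference of 0.38 where random lists ranged from -0.27 to 0.12 between their 1st and 99th percentiles. Its largest members were the collagen-binding proteins Fmod (3.28), Thbs4 (2.93), Comp (1.93) and Postn (1.55). The TGF-beta list had a median of 0.65, with Ltbp2 at 2.28, Tgfb2 at 1.82 and Inhba at 1.40, and 12 of its 14 genes were higher. The smooth muscle and myofibroblast contractile list had a median of 0.76, led by Acta2 (1.94) and Itga8 (1.90), and the fibroblast list one of 0.38. Beside these groups, the atrial cardiomyocyte list had a median of 0.70 and the Schwann and neuronal list one of 1.02, with Gap43 at 1.58 and Mbp at 1.53. All 6 chondrocyte genes were higher (median 0.69, Chad at 2.68), and the lymphatic endothelial list stood at 0.44, with Ccl21 at 4.42. The complement and antigen presentation list (0.24), immediate early genes (0.25, Egr1 at 2.27) and matrix crosslinking enzymes (0.27) also lay above the 99th percentile. The angiogenesis, senescence and osteogenic lists did so too, at medians of 0.15, 0.26 and 0.70, but these turned to -0.10, -0.03 and -0.03 with another background correction (normexp).

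The mitotic, erythroid and ventricular cardiomyocyte lists were lower on the PBS array, while DNA replication (-0.09, 19.3rd percentile) and the sarcomere list (-0.42, 2.94th percentile) lay within random lists. All 18 mitotic genes were below sham, with a median of -0.61 and with cyclin A2 (Ccna2) at -1.54 and Ube2c at -1.15. All 5 erythroid genes were lower, with a median of -1.02, among them the band 3 anion exchanger Slc4a1 (-1.48) and the haemoglobin chaperone Ahsp (-1.43). The interferon list had a median of -0.38 (Usp18 -0.98, Oas1a -0.92) and the T and NK cell list one of -0.50 (Gzmb -1.19). All 12 ventricular and general cardiomyocyte genes were lower, with a median of -0.49, and all 24 genes of mitochondrial respiration were lower, with a median of -0.41. Bright genes ran low on the PBS array as a class, so the random lists matched to these last lists reached -0.46 and -0.39 at their 1st percentiles.

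In all, 624 of 16953 features well above background on both arrays were 2-fold apart, 380 higher and 244 lower, and 20 of 45 lists lay outside the 1st to 99th percentile of random lists. The difference has no replicate check. For scale, the treated arrays, which share a condition, were 2-fold apart at 239 of 17282 features, and the PBS array correlated least with sham across features (r = 0.988, against 0.994 for the treated pair).

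**Figure D1:**
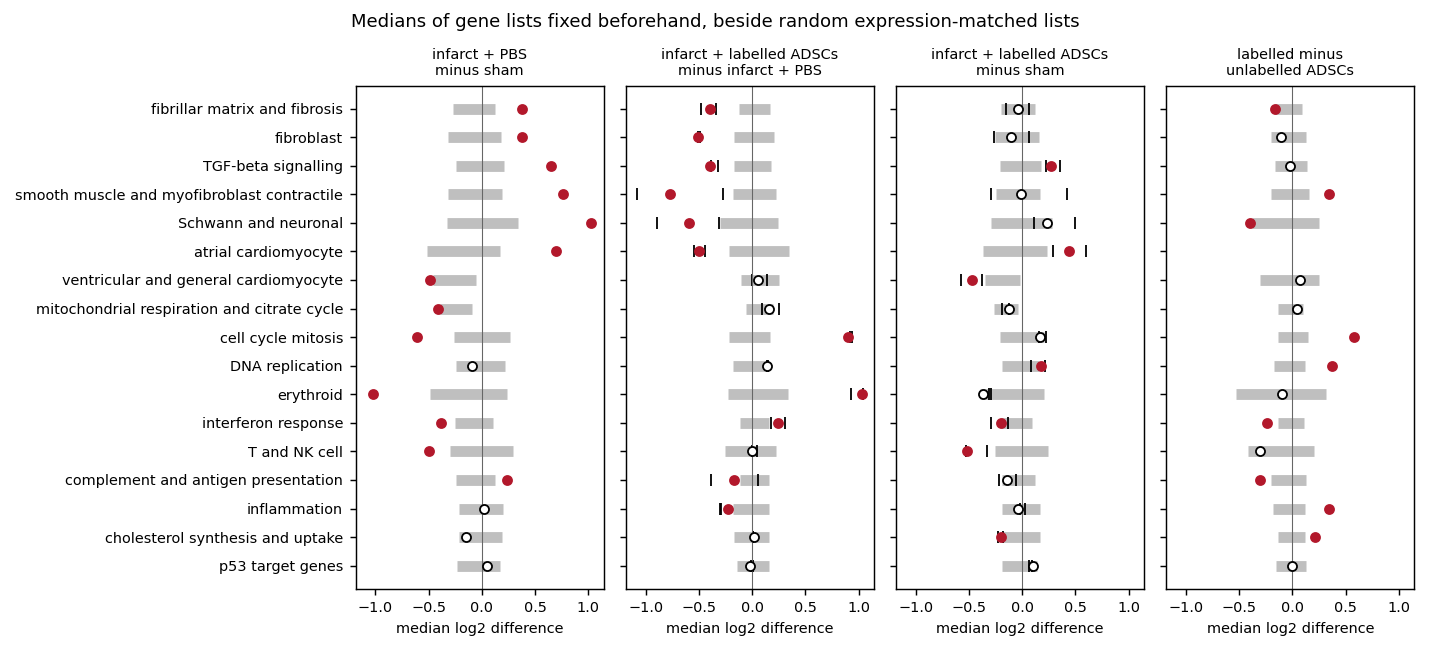
Median log2 difference (horizontal axis) of 17 gene lists in the 4 comparisons: circles are medians, filled where outside the 1st to 99th percentile range of random lists drawn as a grey bar, and vertical ticks are the medians of the 2 treated arrays taken singly. The mitotic list sits at -0.61 for PBS against sham and at 0.90 for treated against PBS, 2 comparisons that share the PBS array.

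The second comparison asked how infarcted myocardium that received labelled ADSCs differed from PBS-injected myocardium. Many genes at the top of the PBS array were lower in both treated arrays, though Btla was not, with a signal of 6.70 on the PBS array and 6.82 in the treated pair. Genes picked as high on 1 array tend to be lower on others. Arrays simulated with no effect also had 24.0% of features high on PBS 2-fold back towards sham. That simulation took its noise from the treated pair (SD of the difference 0.316) and counted only features past 2-fold. It held 127 features high on PBS, against 371 observed. It did not address larger differences, such as those that follow. Myl7 was lower by a log2 difference of -6.17 ± 0.84 (SD, n = 2; limma adjusted p = 0.231), and Rab15 by -5.15 ± 0.10 (adjusted p = 0.0936). By bounds on the mean of the treated pair, Mybphl was at least 231-fold lower, Wfdc21 144-fold and Atp1b4 85.8-fold. Bmp10, a growth factor of atrial muscle, was at least 37.3-fold lower and Bcan 27.0-fold. The limma adjusted p values of these genes lay between 0.0936 and 0.0948. Mybphl had log2 differences of -7.6 and -8.1 in replicates 1 and 3, so its bound did not hold in replicate 1. Next, ranked by the smaller of the differences in the treated arrays and given as means, came Reg3b (-4.04), Rbp4 (-3.40), Sbk2 (-3.40), C4a (-3.39), Gpr15lg (-3.22), Hamp (-3.66), Ccn5 (-3.14) and Cdhr1 (-2.98). By bounds on the mean of the treated pair, Ly6cl1 was at least 7.62-fold, Nrg1 6.55-fold and Sftpc 4.59-fold higher. The treated arrays lay far apart, so these bounds did not hold in each: log2 differences in replicates 1 and 3 were 1.39 and 4.47 for Ly6cl1, 3.28 and 2.14 for Nrg1, and 1.04 and 3.35 for Sftpc. Ranked in the same way and given as means, the highest genes measured on all 3 arrays were Mrpl10, a mitochondrial ribosomal protein (2.01 ± 0.11, limma adjusted p = 0.210), Pla2g2c (1.88), Zbtb16 (1.83), Card9 (1.55), Ccna2 (1.56), Dio3 (1.63), the mitotic gene Cep55 (1.40), Lrtm2 (1.58), the mitotic gene Spc25 (1.35) and Cfap52 (1.85 ± 0.76).

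By list, mitotic genes were higher and matrix genes lower with camera's preset correlation, whose p-values set list genes against other genes, not hearts against hearts. No list in this paragraph passed with an estimated correlation (adjusted p = 0.719, or 0.739 for the macrophage list). That setting called 0% of simulated lists moved by 0.5, so failing it does not count against a list moved by that much. Larger shifts were not simulated. All 18 mitotic genes were above the PBS array in both treated arrays, with a median of 0.90 (camera adjusted p = 2.23e-13, but adjusted p = 0.719 with an estimated correlation). Its members included Ccna2, Ttk (1.40 ± 0.18), Ube2c (1.17 ± 0.11) and Cdk1 (1.17 ± 0.21), and 16 of its 20 tested members passed when adjusted over the list alone, against 0 over all features. The erythroid list had a median of 1.03 (adjusted p = 0.0115), the interferon list one of 0.24 (0.00142) and the DNA replication list one of 0.14 (0.00139), which lay within matched random lists (97.8th percentile). These 3 calls too were lost with an estimated correlation (adjusted p = 0.719). The fibrillar matrix list had a median of -0.40 (2.92e-08), with 18 of 20 genes lower in both arrays, among them Fmod at -2.60 ± 0.61, Comp at -1.72 ± 0.13 and Postn at -1.66 ± 0.24. The fibroblast list had a median of -0.51 (5.42e-06) and the TGF-beta list one of -0.40 (0.00172), and each of these 3 calls went to an adjusted p of 0.719 with an estimated correlation. The contractile list had a median of -0.77 (0.00659), with the treated arrays taken singly at -1.08 and -0.27. Beside them, the atrial list stood at -0.50 (1.96e-05) and the mesothelial list passed as lower (5.42e-06). In PBS against sham, only 4 mesothelial genes were measured on both arrays, 2 higher and 2 lower, too few for a percentile. Camera also took in genes well above background on fewer arrays, so a shift of the whole mesothelial list was not shown. The macrophage list was lower at -0.26 (0.0168), with Trem2 at -0.73 ± 0.03. Lower as well were the lymphatic endothelial (-0.76, 0.0115), Schwann and neuronal (-0.59, 0.00659) and fast skeletal muscle (-0.53, 0.00931) lists. The chondrocyte (-0.26, 0.00142) and adipocyte (-0.09, 0.00155) lists passed as lower but lay within random lists, at the 6.26th and 12.5th percentiles.

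No gene passed in limma at an adjusted p under 0.05 among 19235 features, while 1854 had an unadjusted p under 0.05, where 962 would be met by chance. Other fits gave more: 80 genes with normexp and 57 with a trended, robust spread. With camera, 22 of 47 lists passed, 6 higher and 16 lower. None of the 22 held with an estimated correlation, a setting that also called 0% of simulated lists moved by 0.5. The 1 residual degree of freedom comes from the treated pair, so the lone PBS array was assumed to vary like it. By size alone, 212 of 17027 features were 2-fold apart from PBS in both treated arrays, 72 higher and 140 lower. In simulated data held to the same filter of 17027 features, with spreads drawn regardless of brightness, 198 unchanged features met this rule.

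**Figure D2:**
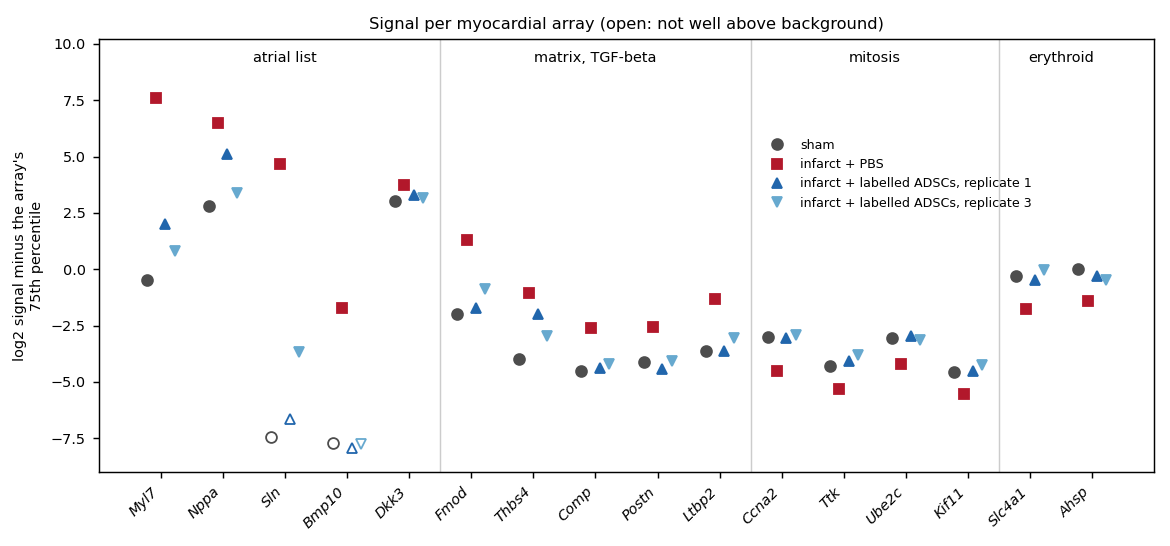
Signal of 16 genes on each of the 4 myocardial arrays, as log2 minus the array's 75th percentile (vertical axis), with 1 symbol per array and open symbols for values not well above background. Myl7 lies at 7.60 on the PBS array and at -0.47 in sham, with the treated arrays at 2.02 and 0.83.

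The third comparison set treated against sham myocardium. Taken singly, the treated arrays were 2-fold apart from sham at 373 and 408 features, against 624 for the PBS array. By the same ranking, the highest genes measured on all 3 arrays were, with mean differences, Btla (3.86 ± 0.01, limma adjusted p = 0.238), Mrpl10 (2.76 ± 0.11, 0.238), Caly (2.43), Slc6a12 (1.80), Sfrp2 (1.72), Gad1 (1.86), the zinc finger factor Egr1 (1.97), Rtel1 (1.70) and Cxcl14 (1.71). Btla, named as an inhibitory lymphocyte receptor, was read from the brighter of its 2 probes, and the other was not looked at singly. The T and NK cell list was lower. Or4c122, an olfactory receptor of a large family, stood at 1.52, and at -0.15 with normexp. By bounds on the mean of the treated pair, Sftpc was at least 9.84-fold and Rpl39l1 6.74-fold higher. Log2 differences in replicates 1 and 3 were 2.33 and 4.64 for Sftpc, and 2.63 and 2.88 for Rpl39l1. Among the lowest measured on all 3 were C2h3orf33 (-3.22 ± 0.22, 0.238), Klk1c2 (-2.24), Cd1d1 (-2.12), Avp (-1.90), C6 (-1.84), Myo16 (-1.77), Polr3c (-1.76), Zfp157 (-1.52) and the granzyme Gzma (-1.48). By bounds on the mean of the pair, Lrr1 was at least 43.6-fold, Kcnk10 12.0-fold and Fam228a 10.6-fold lower. Kcnk10 had log2 differences of -3.84 and -3.35 in replicates 1 and 3, so its bound did not hold in replicate 3.

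All 12 ventricular and general cardiomyocyte genes were lower in both treated arrays, with a median of -0.47 (camera adjusted p = 0.000359, but 0.909 with an estimated correlation), among them Tnnt2 (-0.70 ± 0.08) and Myh6 (-0.61 ± 0.18). The other calls in this paragraph also had an adjusted p of 0.909 with an estimated correlation. The T and NK cell list had a median of -0.52 (0.00798), and mitochondrial respiration one of -0.12 (0.0213), which lay at the 78.3rd percentile of matched random lists. The mast cell list stood at 0.33 (0.00243), with chymase Cma1 at 1.41 ± 0.07, and the TGF-beta list at 0.27 (0.0477), with Tgfb2 at 1.11 ± 0.25. DNA replication stood at 0.18 (0.0477). The neutrophil list was lower (0.0477), with S100a8 at -1.59 ± 0.70. Mitotic genes stood at 0.17 (0.00798), but at -0.07 with normexp. The sarcomere list stood at -0.27 (0.0333), but at 0.01 with quantile normalization. The fibrillar matrix list was within random lists, at -0.04 (54.6th percentile), with Fmod at 0.67 ± 0.61 and Mfap5 at -0.68 ± 0.20.

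Apart from the fibrillar matrix list, those just named are the 9 of 47 lists that passed camera, 4 higher and 5 lower. All 9 were lost with an estimated correlation, a setting that called 0% of simulated lists moved by 0.5 in treated against PBS. With quantile normalization, 4 lists passed. No gene passed in limma, with 1850 at an unadjusted p under 0.05 and 962 met by chance. Other fits gave 50 genes with normexp and 49 with a trended, robust spread. By size, 163 of 16757 features were 2-fold apart from sham in both treated arrays, 97 higher and 66 lower. This balance did not hold in both arrays: replicate 1 alone had 172 higher and 201 lower, and replicate 3 alone 224 and 184.

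Of 371 features 2-fold higher on the PBS array than in sham and measured on all 4 arrays, 94 (25.3%) were 2-fold back towards sham in both treated arrays and 65 (17.5%) were also 2-fold above sham in both. Of 227 that were 2-fold lower, 40 (17.6%) were back and 43 (18.9%) were also below sham. The comparisons share arrays. Arrays simulated with no effect from the spread of the treated pair had 127 higher features, 24.0% back and 23.5% also above, and 126 lower ones, 23.9% back and 23.0% also below. The share that was back lay near the simulated one for higher features and under it for lower ones, and no test was made of these shares. Of the counts, 94 and 65 lay above their simulated ranges (21 to 41 and 20 to 42), 43 just above its own (18 to 41), and 40 within it (19 to 42), but the observed arrays also had more 2-fold features to begin with. Independent lists would share 2.76 and 2.14 of the higher features and 0.913 and 0.886 of the lower. The covariance across features of PBS minus sham with treated minus PBS was -0.107, against -0.0596 simulated, and with treated minus sham 0.104, against 0.0590. What the shared sham and PBS arrays add to these figures cannot be split off.

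The last comparison asked what labelling did to ADSCs in culture. Labelled cells held 38.2-fold more Angptl4 RNA (log2 difference 5.26), a secreted inhibitor of lipoprotein lipase. By bounds, Lrrc34 was at least 11.2-fold, Terb2 9.65-fold, Csf2rb 8.73-fold and Ces2g 7.47-fold higher. Next among genes measured on both arrays came Ch25h, which hydroxylates cholesterol (5.03-fold), the transcription factor Prdm1 (4.39-fold), the retinoic acid hydroxylase Cyp26b1 (3.86-fold), Lmod2 (3.46-fold), Slco4a1 (3.31-fold), Cd83 (2.97-fold), Cpt1a, which brings long-chain fatty acids into mitochondria (2.91-fold), Ush1c (2.87-fold) and the calcineurin regulator Rcan1 (2.79-fold). By bounds, Ccdc172 was at least 12.0-fold, Slc25a54 8.98-fold and Or10d1b 5.74-fold lower. The lowest measured on both arrays were Rbm47 (-2.15), Gap43 (-1.68), Htr2b (-1.67), the monoglyceride lipase Mgll (-1.67), Cyp4f1 (-1.60), Zc3h13 (-1.54), Gja5 (-1.47), Krt87 (-1.43), Wfdc21 (-1.40) and Tcim (-1.39).

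Cell cycle genes were higher as a group in labelled cells. All 20 mitotic genes were above unlabelled cells, with a median of 0.58 (Ccnb2 0.80, Cenpf 0.74), and 22 of 23 DNA replication genes were, with a median of 0.37 (Cdc6 0.92). The inflammation list had a median of 0.34 (Il1rn 1.24, Cxcl1 0.73, Ccl2 0.67), though Cx3cl1 stood at -0.96. The contractile list stood at 0.34, the wall stress list at 0.33, cholesterol synthesis at 0.21 (16 of 20 genes higher) and fatty acid oxidation at 0.14 (16 of 19 higher). Lower lists were the interferon response (-0.24, 19 of 22 genes lower, Mx2 -0.73), complement and antigen presentation (-0.30, C4a -1.12), fibrillar matrix (-0.16, elastin Eln -1.24) and Schwann and neuronal genes (-0.40). The p53 target list stood at 0.00 (54.7th percentile), with Phlda3 at 0.67 and Bax at -0.63, and the mesenchymal stem cell surface marker list at -0.01 (54.9th percentile).

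In all, 185 of 17926 features were 2-fold apart, 80 higher and 105 lower (43.2% higher), and 11 of 41 lists lay outside random lists. The balance of directions depended on the processing: 57.8% were higher with quantile normalization, 57.0% in the authors' own values and 63.8% with normexp, but 44.6% with the mean of a gene's probes, 35.8% at 1.5-fold and 27.9% with no filter on dim probes. With 1 array per condition, the difference has no replicate check, and no replicate pair of cultures was there to set beside it.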

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

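Leaving the PBS array out of the treated against sham fits was chosen only after the data were examined; it gave 0 genes in limma and 7 lists in camera. Of 540 values of named genes under alternatives, 454 counted as unchanged, 57 as moved and 1 as reversed, and 28 reached a limma adjusted p under 0.05. Values with a limma adjusted p counted as unchanged when it was 0.05 or more, however far the difference moved. The other values counted as unchanged within a log2 of 0.22. Of 857 list medians, 816 stayed within 0.22, 35 moved beyond it and 6 reversed. The reversed values came from normexp for Or4c122 in treated against sham (-0.15), for PBS against sham in the angiogenesis (-0.10), osteogenic (-0.03) and senescence (-0.03) lists, and for mitotic genes in treated against sham (-0.07). The sarcomere list in treated against sham reversed to 0.01 with quantile normalization and 0.02 in the authors' values. The median of all features for PBS against sham moved from -0.05 to -0.14 with normexp; other causes were not tested.

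Counts of 2-fold features, in the order PBS against sham, treated against PBS, treated against sham and labelled cells, were 237, 88, 72 and 69 with normexp. Its offset shrinks dim differences by construction, but it also used the median signal, and these choices were not told apart. They were 2247, 800, 798 and 1332 with no filter on dim probes, 2235, 826, 733 and 1151 at 1.5-fold, and 158, 52, 42 and 15 at 3-fold. With 1 treated replicate left out, treated against PBS gave 435 to 498 and treated against sham 373 to 408. Of features higher on the PBS array, those also above sham numbered 24 with normexp and 254 with no filter, and 83 to 122 with 1 replicate left out; those back towards sham numbered 44, 360 and 110 to 161. Of features lower there, those also below sham numbered 21 and 271, with 62 to 64 with 1 replicate left out, and those back 12, 156 and 63 to 67. Under quantile normalization, the authors' values and the mean of a gene's probes, all of these counts stayed within 1.5 times.

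Genes past limma in treated against PBS and treated against sham were 80 and 50 with normexp, and 57 and 49 with a trended, robust spread. Treated against PBS gave 11 at an adjusted p under 0.1; treated against sham gave 3 in the authors' values and 3 with features above background on all 4 arrays. PBS against sham gave 0 in limma with the borrowed spread, beside 2329 at an unadjusted p under 0.05. Lists past camera in treated against sham were 4 with quantile normalization and 3 in the authors' values, and 0 in both contrasts with an estimated correlation. For treated against PBS, that setting called 0% of simulated 20-gene lists moved by 0.5, as of unmoved ones. Its 0 counts therefore do not speak against lists moved by that much. Larger shifts and treated against sham were not simulated. Labelled cells had 17 lists outside the 5th to 95th percentiles. The cause was not tested for the limma and camera counts. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Limma and camera with a treated replicate left out have no residual degrees of freedom and were not run.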

Other observations

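Both tests of infarction alone, that of a lowering by the injected cells and that of the LXR list with every member were chosen only after the result was seen. So was the spread by which list percentiles were judged, the range when each member is left out in turn; the second atrial, second erythroid, PPAR and LXR lists were written after the top genes but before their own values were seen.

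The neutrophil genes S100a8 and S100a9 were lower in infarcted than in sham myocardium whatever was injected: S100a8 stood at -1.56 on the PBS array and at -1.59 ± 0.70 (SD, n = 2) in the treated pair, and S100a9 at -1.40 and -1.35 ± 0.71. Their list had 4 measured genes in PBS against sham, too few for a percentile. All 4 were lower, but only 2 by 2-fold. All rest on 1 sham array. Angptl4, the top gene of labelled cells, also stood above sham in myocardium, by 2.10 on the PBS array and 1.44 ± 0.18 in the treated pair (limma adjusted p = 0.342). In labelled cells, the cholesterol exporters Abca1 (1.29) and Abcg1 (1.31), the uncoupling protein Ucp2 (0.89) and the lipid droplet protein Plin2 (0.72) stood above unlabelled cells. These genes were picked after their values were seen.

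Matrix and atrial genes were high together on the PBS array. For the fibrillar matrix genes only, values went against infarction alone, whatever was injected: their list in treated against sham lay at percentile 54.35 (49.9 to 59.2 with members left out). That does not exclude it, since a high value in the 1 sham array or a difference between pieces could give the same. Infarction alone stays open too for the atrial list, which stood at 0.44 in treated against sham (percentile 99.98), and for the TGF-beta list at 0.27 (99.91). Both comparisons with sham share 1 sham array, so a low value in sham could give the same, and a need for a second sham array was written into that test with this known. Atrial tissue in that piece may account for Myl7, Sln and Bmp10, but a second atrial list, PBS minus the other 3 arrays, lay at percentile 93.79, under the 95 set beforehand as counting against it. Its range with members left out, 55.8 to 99.3, spans that bound, and Kcna5 (-0.72) went against Stard10 (1.27). The same list lay within random lists in PBS against sham (percentile 95.8) and below them in treated against PBS (-0.29, percentile 0.55); the latter goes with atrial tissue but rests on the same PBS array. So atrial tissue is held undecided, a reading adopted after the value was seen; by the bound alone it failed. A lowering by the injected cells cannot be told apart from a difference between pieces, since the atrial list was lower by -0.50 in treated against PBS beside -0.40 for the matrix list, and there is 1 PBS array.

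Angptl4, Cpt1a, Abca1 and Abcg1 were high in labelled ADSCs, 4 genes picked after their values were seen. Lipid genes were not tested as a whole. The cholesterol synthesis (0.21) and fatty acid oxidation (0.14) lists were high, and the adipogenic list stood at -0.03 (44.8th percentile). The single genes Mgll (-1.67) and Cyp4f1 (-1.60), both among the 10 lowest, were low. A spot artefact is argued against, since the lowest labelled Angptl4 spot lay 5.17 (log2) above the highest unlabelled one, with 2 spots of 1 probe per array. A shared response of LXR targets as a set is argued against too. Their list without Abca1 and Abcg1 lay at percentile 3.05 (2.20 to 7.65), and with both kept in at 10.99. Without Abca1 and Abcg1, 9 genes were measured and 3 were higher, Lpcat3 (0.70) and Apoe (0.36) among them. Mylip (-0.67) and Pltp (-0.64) were lower. These values do not exclude a response of Abca1, Abcg1 or other single targets. The PPAR target list without Angptl4 and Cpt1a lay at percentile 99.96, but 13 of its 18 measured genes belong to the fatty acid oxidation list already seen as high, and the other 5 had a median of -0.02 (percentile 45.8). A PPAR response may therefore be present, yet it cannot be told apart from the fatty acid oxidation shift already described, and with 1 culture each the label cannot be told apart from the culture.

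Mitotic genes were low on the PBS array, beside erythroid genes. Fewer erythroid precursors in that piece may account for both, but a second erythroid list, PBS minus the other 3 arrays, lay at percentile 6.78, over the 5 set beforehand as counting against it. Its range with members left out, 0.73 to 9.16, spans that bound, so this too is held undecided after the value was seen, where the bound alone would count against it. The same list lay at percentile 5.53 in PBS against sham and 97.8 in treated against PBS, both within random lists. Klf1 (-0.78) and Hemgn (-0.66) were low while Sptb (0.14) was not. Less cell division in the tissue itself was not tested.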
